A study of Mus musculus with 4 samples.

How the data were processed

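RNA was isolated from mouse lenses with Trizol and made into TruSeq sequencing libraries, per the labels' protocols. The lenses came from C57BL/6 mice of 2 transgenic lines. CRYAAN101D mice express alpha A crystallin carrying N101D, a change that stands for deamidation of that asparagine, and CRYAAWT mice express the unmodified protein. They are called N101D and WT here. Each line gave 1 library at 2 months and 1 at 4 months, so there were 4 libraries and 1 per group. The labels do not say how many animals or lenses went into a library, nor their sex.

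The values are FPKM (fragments scaled to transcript length and to the number of mapped fragments) as the authors deposited them. The submitters' processing notes name CASAVA 1, TopHat 1.2.0, Cufflinks 1.0.3 and Cuffdiff, with mm9 as the genome build. The Cuffdiff version and the annotation were not given in the sources used here. Each table lists 44597 loci with a locus identifier, a gene symbol, a position, a status and the FPKM. The status was the same in both libraries of one age and differed between the ages for 2788 loci, so each age looks like a separate estimation and levels set across ages rest on separately made tables. Loci of status FAIL, 289 at 2 months and 488 at 4 months, are listed at 0 and were treated as missing. Positions are given on mm9 as listed, and whether their starts count from 0 or 1 was not given in the sources used here.

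The loci fall into blocks that follow the strand of the genes: in the first block 95.2% of the genes matched lay on the plus strand and in the second 95.4% on the minus strand. In the third 88.3% lay on the plus strand, and what sets it apart was not given in the sources used here. For named genes it was used only in an alternative that sums all loci of a symbol, and its loci also served for depth and, where they have no symbol, in the closing tests. Of the 21528 symbols, 1016 stood on more than 1 locus of the first and second block (called stranded here), and each took the stranded locus of highest mean FPKM. The 33 loci whose symbol had turned into a date were left out, as were 15488 loci without a symbol. This left 21384 genes, of which 11311 reached 1 FPKM in at least 1 library and were analysed. For 47 of these a value was missing at 1 age. Reads of closely related genes, such as Cryge and Crygf or Hba-a1 and Hba-a2, and of overlapping genes may have been shared between loci by the authors' estimation, and those values are uncertain. The kit named in the labels is not said to mark strand, so reads of a gene and of its antisense partner cannot be told apart. Whether transgene reads count toward mouse Cryaa was not given in the sources used here either.

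Depth was recovered from the FPKM values. Among low values of single loci, FPKM times length moved in steps, taken as 1 read, after 160 to 169 bases were taken off the length. The steps put the N101D libraries at 24.6 M fragments (2 months) and 53.2 M (4 months), and the WT libraries at 49.8 M and 35.0 M. With these, 90.7%, 97.3%, 97.3% and 95.4% of the 2736, 1245, 2406 and 2740 values used came within 0.05 of a whole read, in the order N101D at 2 months, N101D at 4 months, WT at 2 months and WT at 4 months. At 1 FPKM, 1 kb of effective length (the length less these bases) then rests on about 24.6 reads in the shallowest library. The 95% Poisson interval of that number is 15.8 to 36.4. In the deepest library it is 53.2 reads (39.9 to 69.5). A transcript of 1 kb in all rests on fewer reads. These intervals cover counting error only. No counts were rebuilt from these steps, because most loci hold several transcripts of different length.

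Differences were taken as log2(FPKM + 1), a scale that understates the change of genes of low FPKM, with no further scaling. A gene was counted as 2-fold different at an absolute log2 difference of 1 or more. Comparisons of single libraries (genotype at each age, age in each genotype) carry no p-value and have no replicate check, since each group has 1 library. The 1 test that the design allows was a limma fit (limma 3.58.1 in R 4.3.3) with age and genotype as additive terms, a prior that follows mean expression, and Benjamini-Hochberg adjustment over 11264 genes. It has 1 residual degree of freedom, and the prior adds 3.73. In it each age stands in for a replicate of the other, so p-values measure only the spread between these libraries, which may be technical. The residual is the dependence of the genotype difference on age plus sampling. A gene whose genotype difference depends on age can therefore hardly pass. The labels give no replicate numbers that would pair samples of separate groups.

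There were 33 gene lists, fixed before the data were examined as were the tests and the rule for naming genes. They cover the crystallins, fiber membrane and cytoskeleton, lens epithelium, lens transcription factors, fiber denucleation and organelle loss, Na,K-ATPase and ion transport, calcium handling and calpains, the unfolded protein response, cytosolic heat shock proteins, the antioxidant response, apoptosis and p53 targets, the cell cycle, cell adhesion and junctions, lens capsule and matrix, and fibrosis and EMT. Others hold immediate early genes, FGF, BMP and Notch signalling, Wnt and actin regulators, autophagy and lysosome, ubiquitin and proteasome, glycolysis and the sorbitol pathway, oxidative phosphorylation, sterol synthesis, cytosolic ribosomal proteins, replication-dependent histones, and complement and antigen presentation. The remaining lists mark other cells that a dissected lens could carry, namely macrophages and leukocytes, blood, retina neurons, pigmented iris, ciliary body and RPE, cornea and conjunctiva, muscle, and vessels. A list's median log2 difference was placed as a percentile among medians of 10000 random lists of the same size drawn from 20 bins of mean expression. This percentile describes these libraries and is no p-value. In the additive fit the lists were tested with camera (preset correlation of 0.01, then a correlation estimated from the data) and with fry, adjusted over the lists. The estimated correlation has 1 residual degree of freedom behind it.

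Genes were named by rule: per comparison the 10 highest and 10 lowest differences among genes above 0 in both libraries (without small RNA genes and models named only by a clone or number), up to 4 members per list at 2-fold or more, up to 3 genes listed at 0 in either library, every crystallin, and a few genes set beforehand, Atp1b1 and Atp1b3 among them. For the additive fit the rule took the 10 highest and lowest by the smaller of both differences, and the 10 of lowest p in each direction. Genes outside it, among them Sned1, Uox, Mir715, 2610528E23Rik, C230081A13Rik, the Y-linked genes and list members within 2-fold, were named after their values were seen.

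The 2-fold counts, the random lists, limma for genotype and the recovery of depth were tested on simulated data, while camera, fry, the age term and the length correction were not. For N101D against WT at 2 months, with a scatter of 0.25 added, 94.5%, 99.5% and 100% of 200 genes changed by 1.5, 2 and 3 on the log2 scale were counted among 11264 genes, with 40, 51 and 54 unchanged genes counted beside them. The changed genes were drawn from those of mean log2(FPKM + 1) above 3, so these shares do not cover genes of lower FPKM. For lists of 20 genes, with differences simulated independently for each gene, 4 of 100 without a shift fell outside the 95% range of random lists. Of 100 lists shifted by 0.3, 76 lay above it. Lists whose genes move together were not simulated. For genotype over both ages limma called 59.5%, 100% and 100% of 200 genes changed by 1, 2 and 3, with 3, 10 and 12 false calls. All genes of this simulation had the same scatter, and a changed gene differed equally at both ages. The data are not so even, so these shares do not give the power of the fit to the real libraries. Libraries simulated at 25 and 50 M fragments gave 24.9 and 50 M.

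Alternatives were other pseudocounts, filters and thresholds, upper quartile scaling, centring on the median, quantile normalization, equal totals without the crystallins, the sum of all loci of a symbol, and loci of status OK only. For limma they were also a fit without the trend and a fit without the other factor. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. GENCODE annotation of GRCm38 served for strands, names and transcript lengths, and no coordinates were converted.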

Results

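Gene expression was measured by RNA sequencing in lenses of N101D and WT transgenic mice, with 1 library per genotype at 2 months and 1 at 4 months. The 4 libraries held 24.6 M (N101D, 2 months), 49.8 M (WT, 2 months), 53.2 M (N101D, 4 months) and 35.0 M (WT, 4 months) fragments, as recovered from the steps in their FPKM values. At 1 FPKM or more they listed 10057, 10684, 10874 and 10665 genes, in the same order. The design asks which genes differ between lenses with deamidated and unmodified alpha A crystallin at both ages, and age comparisons within each genotype follow from it. Because each group had 1 library, differences between single libraries are given as values with no replicate check.

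Crystallins, the structural proteins that make up most of the soluble protein of lens fibers, took 67.1% of the FPKM of named genes in the N101D library of 2 months and 71.5% in the WT library. At 4 months they took 55.4% and 59.97%. The summed crystallin FPKM was higher in N101D at 2 months (536491 against 473906) and lower at 4 months (233089 against 277005). The lower share at 2 months goes with 10 other genes of high FPKM, described below. They held 98015 FPKM in N101D and 21354 in WT at that age. Cryaa, the mouse gene for alpha A crystallin (XLOC_016433, chromosome 17, 31812400 to 31818669 on mm9), was listed at 67372 FPKM in N101D and 68167 in WT at 2 months. At 4 months it stood at 44741 and 41937 FPKM. The genotypes thus differed by -0.02 and 0.09 on the log2 scale at the ages of 2 and 4 months, and Cryaa gives no check of which transgene a library carried. Cryab, the gene for the partner chaperone alpha B crystallin, differed by -0.06 and -0.14.

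The crystallin list had a median log2 difference of 0.21 in N101D at 2 months (12 of 16 members positive), which turned to -0.26 with equal totals without the crystallins and to -0.16 with quantile normalization. At 4 months the median was -0.35, with 15 of 16 members lower in N101D and Cryaa the exception. This lay at percentile 0.03 among random lists. Among the beta crystallins at 4 months, Cryba1 differed by -0.36, Cryba2 by -0.12, Cryba4 by -0.35, Crybb1 by -0.15, Crybb2 by -0.21 and Crybb3 by -0.39. Among the gamma crystallins, Cryga (chromosome 1, 65146962 to 65150454) was listed at 46.7 FPKM in N101D against 242 in WT, a log2 difference of -2.35, after 1700 against 1026 FPKM at 2 months. Crygb differed by -0.56 at 4 months, Crygc by -0.42, Crygd by -0.49, Cryge by -0.95, Crygf by -0.27, Crygn by -0.13 and Crygs by -0.42.

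**Figure D1:**
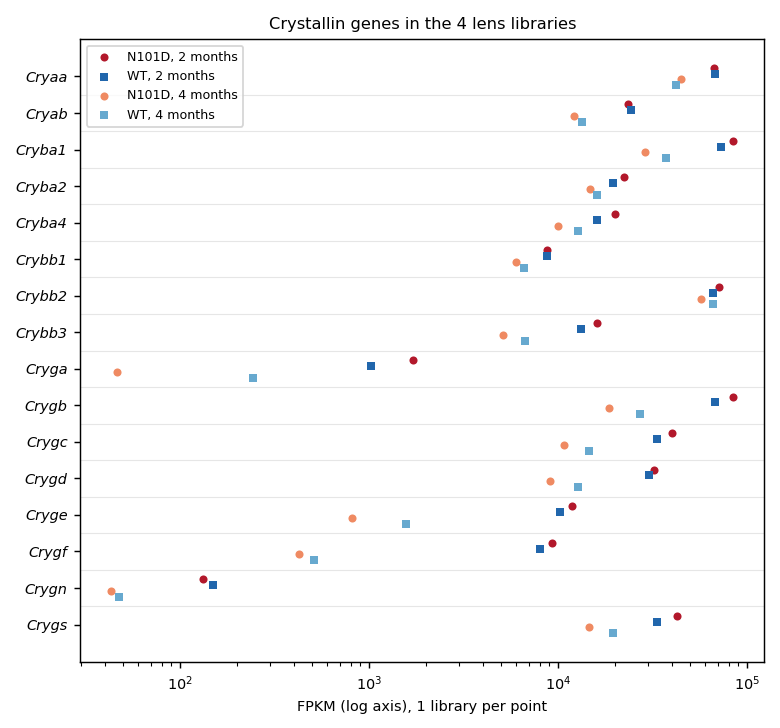
FPKM of the 16 crystallin genes in each of the 4 libraries on a log axis, 1 point per library. Cryaa lies between 41937 and 68167 FPKM in all libraries, while Cryga spans 46.7 (N101D, 4 months) to 1700 (N101D, 2 months).

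At 2 months genes of pigmented ocular tissue and of the immune system and some matrix genes were far lower in the N101D lens library than in the WT library. Gpx3, a secreted glutathione peroxidase (XLOC_005030, chromosome 11, 54716301 to 54776622), was listed at 3.07 FPKM in N101D and 239 in WT, a log2 difference of -5.88. Optc, which encodes the matrix protein opticin, stood at 0.268 against 63.3 FPKM (-5.66). In all, 410 genes were at least 2-fold lower and 46 at least 2-fold higher in N101D among 11291 genes, and the median over all genes was -0.09. With equal totals without the crystallins these counts were 747 and 24, and with quantile normalization 320 and 59.

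Other genes among the lowest were Fbln1 (fibulin, matrix; -5.10), Penk (the enkephalin precursor; -5.08), Slc26a4 (an anion exchanger; -4.56), Mfap4 (microfibril-associated; -4.28) and Apoe (lipid transport; -4.24), the last at 23.4 against 462 FPKM. Zic2, a transcription factor at 6.03 FPKM in WT, was listed at 0 in N101D, as were Oxtr (2.24 FPKM in WT) and Slc39a5 (1.87). All 14 measured markers of pigmented iris, ciliary body and retinal pigment epithelium were lower in N101D, 9 of them by 2-fold or more, with a median of -2.61 (percentile 0). They include the melanin genes Dct (3.17 against 138 FPKM) and Pmel (1.75 against 47.6), and the melanosomal genes Gpnmb (2.59 against 81.8) and Mlana (0.596 against 26.8).

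Beside these markers, 10 of 16 complement and antigen presentation genes were at least 2-fold lower, with a median of -1.41 (percentile 0). Examples were Cd74, the chaperone of class II molecules (-2.64), Ifit3, an interferon-induced gene (-2.55), B2m (-2.15) and the complement gene C1qa (-2.01). Macrophage and leukocyte markers had a median of -1.08 (4 of 6 at least 2-fold lower), among them Lcn2 (-1.44), Tyrobp (-1.20), Csf1r (-1.09) and Fcer1g (-1.06). Blood genes had a median of -1.22, with Hba-a1 at -1.55 and Hba-a2 at -1.54. Vessel markers had a median of -0.83 (Rgs5 -1.76, Flt1 -1.47) and cornea and conjunctiva markers -0.82 (Dcn, the gene for decorin, -1.46), but vessel markers turned to 0.18 among genes filtered at 5 FPKM. With loci of status OK only, vessel markers stood at 0.33 and cornea markers at 0.80. Retina neuron markers stood at -0.15. Muscle markers had a median of 0.00.

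FGF, BMP and Notch signalling genes had a median of -0.28 at 2 months (percentile 0.09), with 4 of 25 at least 2-fold lower. These were Bmp4, a secreted ligand (-2.02), the Notch ligand Dll1 (-1.96), the Notch target Hes1 (-1.25) and the receptor Notch3 (-1.21). Fibrosis and EMT genes had a median of -0.27, with Col1a1 at -2.14 and Col1a2 at -1.84. Lens capsule and matrix genes had a median of 0.05, yet Col18a1 stood at -3.28 and Nid2 at -1.33. The antioxidant list had a median of -0.02, and its 3 genes at 2-fold or more were Gpx3 and the metallothioneins Mt2 (-1.70) and Mt1 (-1.59). Lens epithelium genes had a median of 0.05, with Igfbp5 at -1.92 and the gap junction gene Gja1 and the keratin gene Krt18 both at -1.18. Cell adhesion and junctions stood at -0.11 (Cldn1, a claudin, -2.17) and Wnt and actin regulators at -0.07 (the co-receptor Lrp5, -1.06). Atp1b1 differed by -0.76 at 2 months and -0.04 at 4 months and Atp1b3 by -0.05 and 0.17, while Atp1b2 (-1.13) and the bicarbonate transporter Slc4a4 (-1.49) were lower at 2 months. Their list, Na,K-ATPase and ion transport, had medians of -0.14 at 2 months and 0.04 at 4 months.

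The genes higher in N101D at 2 months were few and several had very high FPKM. Kpna1, a nuclear import receptor gene, was listed at 8477 against 1757 FPKM (log2 difference 2.27) and Filip1l at 8620 against 2215 (1.96). Zc3h7a (2.24), Jarid2, a gene of the polycomb system (2.18), Lars2, the mitochondrial leucyl-tRNA synthetase (2.12), the dynein gene Dnahc7b (2.35) and Vwa3a (2.35) differed by nearly the same amount. Second loci on the same strand differed little for Zc3h7a (4.92 against 4.47 FPKM), Jarid2 (7.45 against 6.54) and Dnahc7b (2.12 against 1.90). On the other strand, loci of Zc3h7a (872 against 169 FPKM) and Jarid2 (3188 against 715) were higher too. Filip1l shares its listed span with 2610528E23Rik on the other strand. Xist, the RNA that silences an X chromosome in females, stood at 12.9 FPKM in N101D and 0.0744 in WT at 2 months, and has no usable value at 4 months. The Y-linked genes Ddx3y (0.303 FPKM in N101D; -3.08), Eif2s3y (0.122 against 11.6), Kdm5d (0.0690 against 1.94) and Uty (0.0367 against 2.46) were lower in N101D at that age. At 4 months all 4 Y-linked genes were listed above 1 FPKM in both genotypes. By these genes the N101D library of 2 months looks female, while the other libraries hold male tissue. Genotype at 2 months and age in N101D are therefore confounded with sex. Sh3rf1 (5.83 against 0.591 FPKM) and Rpl39l (2.26 against 0.0223) were also higher, but a second Sh3rf1 locus on the other strand stood at 0.992 against 2.94. The ribosomal protein list had a median of 0.17 at 2 months, which turned to -0.29 with equal totals without the crystallins.

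**Figure D2:**
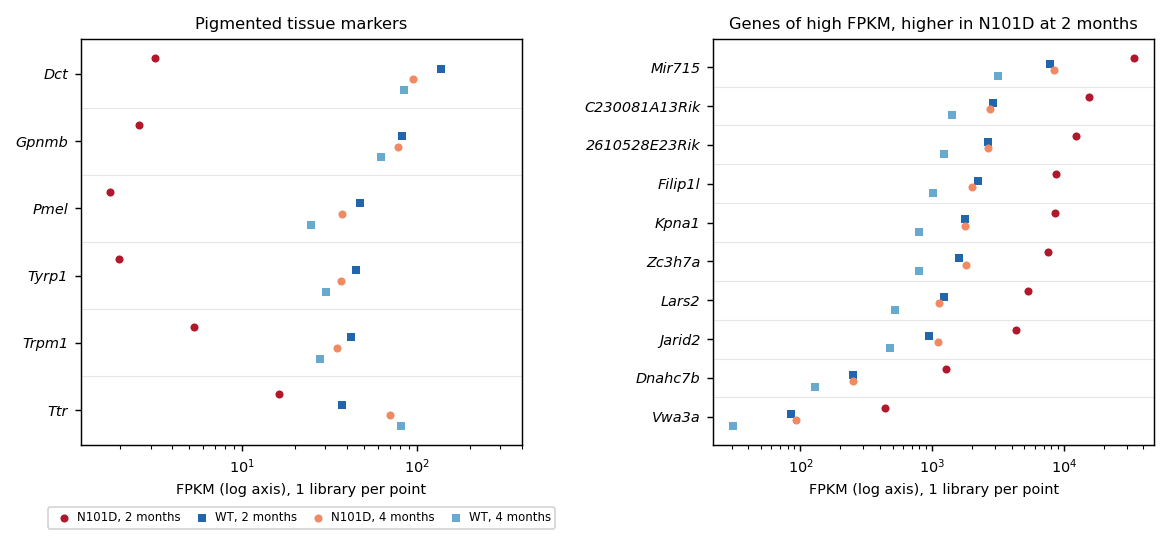
FPKM on a log axis of genes of pigmented tissue and of the genes of high FPKM that were higher in N101D at 2 months, 1 point per library. The N101D library of 2 months stands apart in both, with Dct at 3.17 FPKM against 84.2 to 138 in the other libraries and Kpna1 at 8477 against 790.0 to 1786.

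At 4 months the lens libraries of both genotypes were closer to each other, with 38 genes at least 2-fold higher and 32 lower in N101D among 11284 genes (71 higher with the sum of all loci of a symbol). Immediate early genes, which respond within minutes to growth factors and stress, were higher in N101D: Fos (chromosome 12, 86814797 to 86818219) stood at 5.29 against 0.726 FPKM (1.87), Egr1 at 9.24 against 2.36 (1.61) and Junb at 7.86 against 2.90 (1.18). In all, 14 of the 15 measured members were higher in N101D and their median was 0.59 (percentile 100). At 2 months the same list had a median of 0.04, which turned to -0.02 among genes filtered at 5 FPKM and to -0.29 with equal totals without the crystallins. Retina neuron and cytosolic ribosomal protein genes were lower in N101D beside them, at medians of -0.64 and -0.45.

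Malat1, a nuclear noncoding RNA, was listed at 549.9 FPKM in N101D against 161 in WT (1.76). Efha1, which encodes a regulator of mitochondrial calcium uptake, stood at 21.3 against 4.59 FPKM (1.99), though a locus of the same symbol on the other strand stood at 15.0 against 27.7, in the opposite sense. The type I collagen gene Col1a1 stood at 5.22 against 0.586 FPKM (1.97), Cgn, the tight junction gene cingulin, at 9.86 against 2.14 (1.79) and Syce2 at 4.78 against 0.941 (1.57). Haemoglobin genes were higher too, with Hba-a1 at 1.38, Beta-s at 1.37, Hba-a2 at 1.34 and Hbb-b1 at 1.19, and the blood list had a median of 1.26. Among markers of other tissues, Krt12, the keratin of corneal epithelium, was higher by 1.12 and Myh11, smooth muscle myosin, by 1.08. The medians of these lists were 0.43 for cornea and conjunctiva, 0.23 for muscle, 0.32 for vessels and 0.25 for macrophages and leukocytes. Pigmented tissue markers, far apart at 2 months, had a median of 0.14 at 4 months.

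On the lower side at 4 months stood Cryga, Timp1, an inhibitor of metalloproteinases (0.877 against 6.19 FPKM; -1.94), and Dock2, a Rac activator of leukocytes (-1.96; a locus on the other strand stood at 0.371 against 0.0442 FPKM). Mtcp1 (-1.59), the ubiquitin ligase gene Lnx1 (-1.46), the cone transducin subunit Gngt2 (-1.43), Ccdc101 (-1.41), the phosphatase gene Cdc14b (-1.40) and Slc25a13, a mitochondrial aspartate-glutamate carrier (-1.31), followed. Slc39a5 at 1.91 FPKM in N101D and Rpl39l at 0.0411 were listed at 0 in WT, and Rab43 was listed at 0 in N101D against 0.212. Of 27 ribosomal protein genes 26 were lower in N101D, among them Rpl10a (-0.90), Rps27a (-0.85) and Rpl23 (-0.80). Of 22 retina neuron markers 21 were lower, such as Sag (-0.95) and Nrl (-0.92). Oxidative phosphorylation genes had a median of -0.19 (16 of 18 negative) after 0.09 at 2 months. Lens capsule and matrix genes had a median of 0.24 (percentile 100), with 15 of 16 positive and the laminin gene Lama5 at 0.72, and FGF, BMP and Notch genes had 0.15. Complement and antigen presentation stood at 0.18 and fibrosis and EMT at 0.13.

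Stress and protein quality control lists differed little between genotypes, and apart from the antioxidant list none of the lists of this group had a 2-fold member at either age. The unfolded protein response had a median of -0.16 at 2 months and -0.02 at 4 months, with the chaperone gene Hspa5 at -0.14 and -0.32 and the pro-apoptotic factor Ddit3 at -0.39 and -0.02. Cytosolic heat shock proteins stood at -0.13 and -0.08, apoptosis and p53 targets at 0.04 and -0.07, and the antioxidant response at -0.07 at 4 months. Autophagy and lysosome genes stood at -0.13 and -0.05, ubiquitin and proteasome at -0.03 and -0.13, and calcium handling and calpains at -0.14 and -0.01. In the fiber cell itself, fiber membrane and cytoskeleton genes stood at 0.00 and -0.12 (Gja3 0.12 and -0.14, Lim2 0.24 and -0.28, Bfsp1 -0.15 and -0.13). Denucleation and organelle loss genes stood at 0.05 and -0.11 and lens transcription factors at 0.04 and 0.11. Lens epithelium and cell adhesion stood at 0.08 and 0.02 at 4 months, Wnt and actin regulators at 0.04. The cell cycle list stood at 0.08 and 0.15, the first of which turned to -0.22 with equal totals without the crystallins and to -0.16 among genes filtered at 5 FPKM. Glycolysis and the sorbitol pathway stood at -0.06 and 0.01, sterol synthesis at -0.08 and -0.02, and replication-dependent histones at -0.06 and -0.16, the latter turning to 0.02 without a filter.

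**Figure D3:**
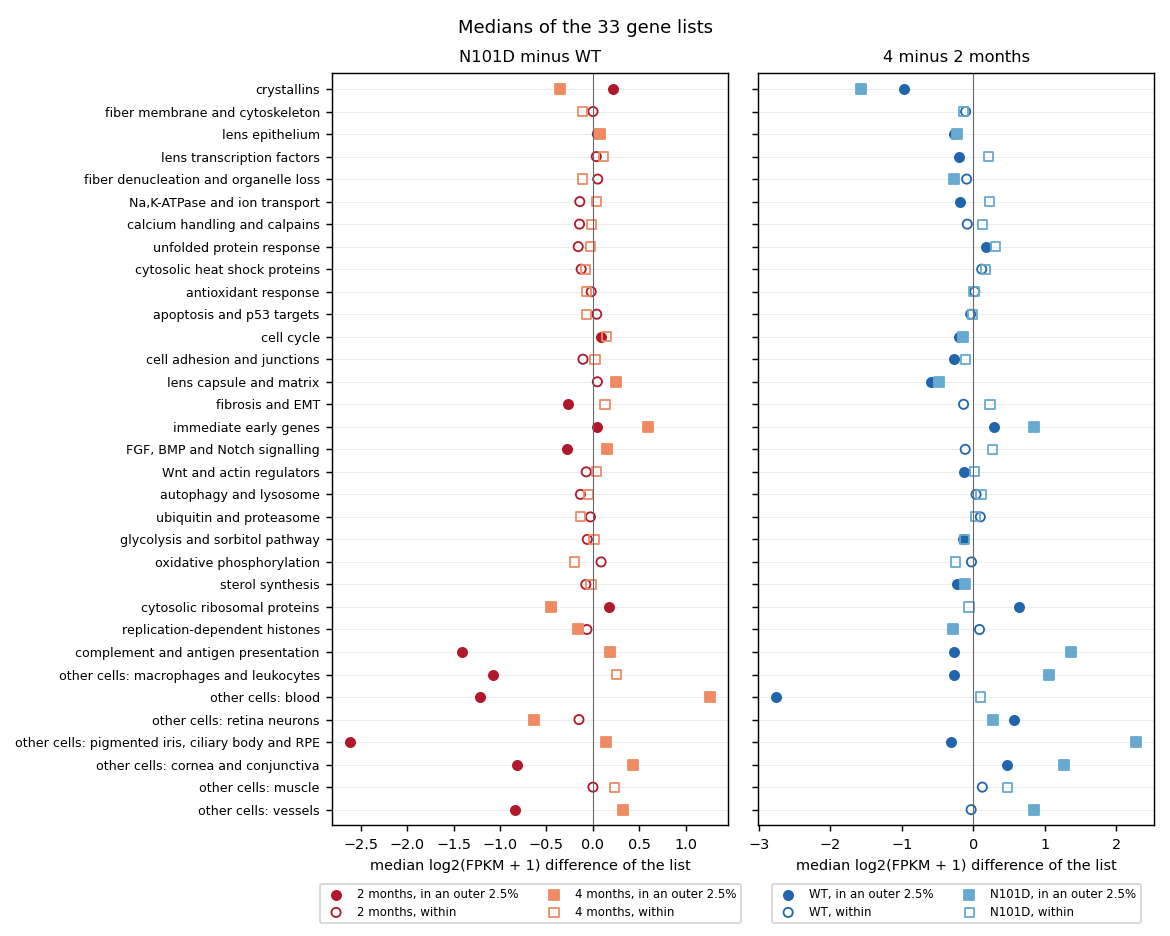
Median log2(FPKM + 1) difference of each of the 33 gene lists in the 4 comparisons of single libraries, with random lists of the same size as the reference. Pigmented tissue markers reach -2.61 for genotype at 2 months and 0.14 at 4 months, and immediate early genes 0.04 and 0.59.

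Few genes differed by genotype in the same direction at both ages. Across 11264 genes the differences at 2 and 4 months had Pearson's r = -0.27 and a Spearman correlation of -0.34, computed across genes, which are not independent replicates. Of these genes 37.0% had the same sign at both ages. Jarid2, Kpna1, Zc3h7a, Lars2, Vwa3a, Mir715 and 2610528E23Rik were at least 2-fold higher in N101D at both ages (7 genes, against 0.152 for independent lists). All 7 belong to a group of 10 genes of high FPKM that shared 1 profile over the libraries, so they are not 7 separate findings. No gene outside that group was 2-fold higher at both ages. Lower at both were 4 genes, against 1.12, with Gngt2, Nudt17 and Slc25a13 among them. Against these, 8 genes were 2-fold different in opposite directions: Dock2, Uox and Dffb were higher at 2 and lower at 4 months (0.124 for independent lists), and Sned1, Slc39a5, Hba-a1, Hba-a2 and Col1a1 the reverse (1.38). The genotype difference at 4 months exceeded that at 2 months by 1 or more for 671 genes and fell short of it by as much for 143 (1279 and 53 with equal totals without the crystallins), values for which no test exists with these libraries.

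**Figure D4:**
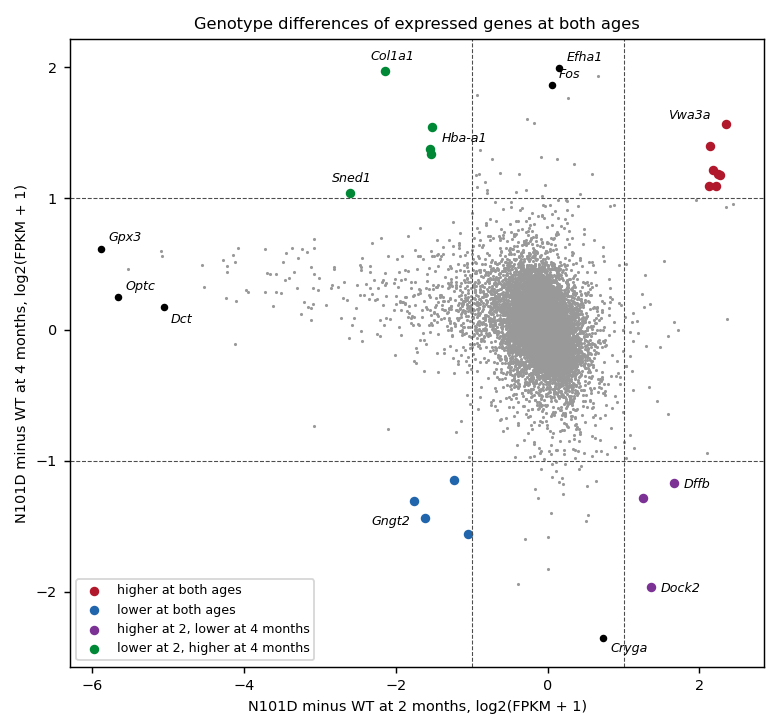
N101D minus WT at 2 months (horizontal) against 4 months (vertical) in log2(FPKM + 1), 1 point per expressed gene. Most spread lies along the horizontal axis, from Gpx3 at -5.88 to C230081A13Rik at 2.44, and across genes r is -0.27.

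In the additive limma fit no gene passed an adjusted p of 0.05 for genotype, and 118 genes had an unadjusted p under 0.05 among 11264. A genotype difference that depends on age counts as residual spread here, so the fit does not speak against differences at a single age. With equal totals without the crystallins, a fit added after the data were seen and with an infinite prior df, 61 genes passed. The genes of lowest p were again those of the shared high-FPKM group and a few of low FPKM. Vwa3a was higher in N101D by 1.96 ± 0.24 (SE; adjusted p = 1), Jarid2 by 1.70, Mir715 by 1.77 and Gpr173, an orphan receptor gene, by 0.91, the last also higher at each age by 0.87 and 0.95, though a Gpr173 locus on the other strand stood at 1.13 against 2.20 FPKM at 2 months. Carf (0.82 and 0.95) and Zfp52 (0.73 and 0.63) followed. Lower in N101D were Gngt2 (-1.52 ± 0.20), Slc25a13 (-1.54), Nudt17 (-1.19), Enoph1, an enzyme of methionine salvage, Sgsm2 (-0.99), Trmt1 (-0.79), Yipf2 (-0.76), the synaptic gene Snap25 (-0.66) and the visual cycle gene Rpe65 (-0.65), all at an adjusted p of 1. Tnip1 (-2.11 at 2 and -0.76 at 4 months) and Ptx3 (-1.14 and -0.70) were lower at both ages.

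Camera with its preset correlation called 6 lists for genotype, and none of them with an estimated correlation. Retina neuron markers were lower in N101D by a median of -0.46 (adjusted p = 1.47e-16, and adjusted p = 0.933 with an estimated correlation). The same estimated value, adjusted p = 0.933, applied to the others: pigmented tissue (median -1.21, preset adjusted p = 3.48e-09) and complement and antigen presentation (-0.55, 1.35e-05) were lower, and immediate early genes (0.23, 6.88e-06), lens capsule and matrix (0.12, 0.00269) and cell cycle (0.07, 0.0397) were higher. By fry the lowest adjusted p was 0.417. No member of any list passed when adjusted over the list alone, as over all genes. Among the lists called, the median, the mean and camera's direction had the same sign. They differed for 8 lists that were not called: lens epithelium, denucleation, FGF, BMP and Notch, Wnt and actin regulators, glycolysis, histones, blood, and cornea and conjunctiva.

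From 2 to 4 months in WT lenses the gamma crystallins were lower and ribosomal protein genes higher. Crygf (chromosome 1, 65972995 to 65974878) was listed at 8052 FPKM at 2 months and 512.5 at 4 months, a log2 difference of -3.97. Cryge differed by -2.71 and Cryga by -2.08. All 16 crystallins were lower at 4 months, 7 of them by 2-fold or more, with a median of -0.97 (percentile 0), and Cryaa stood at -0.70. All 27 ribosomal protein genes of the list were higher, with a median of 0.64 (percentile 100), among them Rplp2 (1.13) and Rps19 (1.04). Of 11264 genes 76 were at least 2-fold higher and 54 lower. The tables of the ages were made separately, which limits levels set across them.

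Higher at 4 months in WT were Serpinb6b, a protease inhibitor gene (5.09 to 31.1 FPKM; 2.40), Tinag, a basement membrane gene (2.09), Psca (1.87), Ccdc101 (1.85), Cdc14b (1.81), the sulfotransferase gene Sult2b1 (1.74), Dffb, the caspase-activated nuclease (1.71), Rps29 (1.68) and Dock2 (1.54), though its locus on the other strand was lower (0.610 to 0.0442 FPKM). The joint locus of Gga3 and Nup85 stood at 1.55. The peroxidase gene Prdx6 was higher by 1.08, from 73.7 to 157 FPKM. The haemoglobin genes Beta-s (-2.93), Hba-a1 (-2.83), Hba-a2 (-2.77) and Hbb-b1 (-2.74) were lower and gave the blood list a median of -2.75. Pgam2, a glycolytic enzyme gene of muscle, was listed at 114 and then 19.3 FPKM (-2.50). Efha1 (-2.35), the hyaluronan-binding Tnfaip6 (-1.97), Crygn (-1.63), Ndufa1 of complex I (-1.09) and the calpain gene Capn3 (-1.02) were lower as well. The other Efha1 locus was higher with age, from 11.98 to 27.7 FPKM. Capsule and matrix genes had a median of -0.59 (15 of 16 negative), with the collagen IV genes Col4a2 at -1.11 and Col4a1 at -1.02. The type I collagen genes Col1a1 (-1.78) and Col1a2 (-1.27) were lower too, in a fibrosis list with a median of -0.14. Retina neuron markers had a median of 0.57 (Pde6g 1.02), and the pigment epithelium genes Rpe65 (1.48) and Ttr (1.09) were higher within a pigmented list of median -0.31. Krt12 was higher by 1.39 among cornea markers of median 0.48. Itga1 and Slc39a5 were listed at 0 at 4 months, after 1.14 and 1.87 FPKM, and Rpl39l at 0 after 0.0223.

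Lens epithelium genes (median -0.27), cell adhesion (-0.27), sterol synthesis (-0.23), cell cycle (-0.20), lens transcription factors (-0.20) and Na,K-ATPase and ion transport (-0.18) were lower with age in WT, each under percentile 1 of random lists. Immediate early genes stood at 0.29, the unfolded protein response at 0.17, complement and antigen presentation at -0.28, and macrophages and leukocytes at -0.27. Wnt and actin regulators and glycolysis stood at -0.14, FGF, BMP and Notch genes and fiber membrane and cytoskeleton genes at -0.11, and heat shock proteins at 0.12. Ubiquitin and proteasome stood at 0.10, and muscle at 0.13. The denucleation, calcium, apoptosis, autophagy, oxidative phosphorylation, antioxidant, histone and vessel lists lay between -0.09 and 0.09.

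From 2 to 4 months in N101D lenses many of the genes with the largest differences were ones that had been low in the 2-month library. Gpx3 (3.07 to 212 FPKM; 5.71), Optc (5.21), Penk (5.10), Fbln1 (4.89), Slc26a4 (4.61), Dct (4.53), Gpnmb (4.46), the acute phase gene Serpina3n (4.34) and the extracellular superoxide dismutase gene Sod3 (4.30) were highest. In all, 587 genes were at least 2-fold higher and 124 lower of 11264, so 82.6% of these were higher, against 69.6% with upper quartile scaling (462 and 202), 68.7% with quantile normalization (408 and 186) and 96.5% with equal totals without the crystallins (1427 and 51). The median over all genes was 0.15 and moved to 0.02 with upper quartile scaling, to -0.03 with quantile normalization and to 0.51 with equal totals, while that of genotype at 2 months moved from -0.09 to 0.02, 0.04 and -0.46 in the same order. Of the 410 genes lower in N101D at 2 months, 339 were at least 2-fold higher at 4 months here, but both comparisons share the N101D library of 2 months, which favours such an overlap. Pigmented tissue markers had a median of 2.28, complement and antigen presentation 1.37, cornea and conjunctiva 1.26 (Krt12 3.35, Lum 1.26), macrophages and leukocytes 1.06 and vessels 0.85 (Cldn5 1.44), but complement turned to -0.32 and vessels to -0.02 with loci of status OK only.

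The gamma crystallins were lower with age in N101D too. Cryga was listed at 1700 and then 46.7 FPKM (-5.16), Crygf differed by -4.46, Cryge by -3.87 and Crygb by -2.19. All 16 crystallins were lower, 11 by 2-fold or more, with a median of -1.57, though Cryba4 (20125 to 10049 FPKM) turned to 0.44 with quantile normalization. Other genes lower at 4 months were Tnfaip6 (-2.86), the pyrimidine enzyme gene Dpys (-2.63), the protease gene Pappa (-2.25), the anti-apoptotic Birc7 (-1.26), the death receptor gene Fas (-1.23), S100a4 (-1.21), Npnt (-1.10), and Dnase2b, the nuclease of fiber denucleation (-1.01). Ndufa1 (-1.67), Ndufa4 (-1.08) and Cox6c (-1.03) were lower in an oxidative phosphorylation list of median -0.25. Col4a1 (-1.19) was lower and Lamb2 (1.11), Agrn (1.09) and Nid2 (1.39) higher in a capsule list of median -0.48. Immediate early genes had a median of 0.84, with Egr1 at 2.75, Junb at 2.39, Fos at 2.14 and Ier2 at 1.16. Prdx6 (1.46) and Ddit3 (1.09) were higher, and the unfolded protein response had a median of 0.31. The tables of the ages were again made separately.

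The other lists with age in N101D gave medians of 0.26 for FGF, BMP and Notch, 0.23 for Na,K-ATPase, 0.23 for fibrosis and EMT (Tagln 1.93, Postn 1.16), 0.22 for lens transcription factors, 0.48 for muscle and 0.28 for retina (Rlbp1 1.36). Heat shock proteins stood at 0.17, calcium handling at 0.13, autophagy at 0.11, blood at 0.10, ubiquitin at 0.03, Wnt at 0.02, the antioxidant list at 0.01, apoptosis at -0.01 and ribosomal proteins at -0.06. Cell adhesion stood at -0.11, glycolysis at -0.12 and fiber membrane at -0.14. Lens epithelium stood at -0.23, denucleation at -0.27, cell cycle at -0.14, sterol synthesis at -0.12 and histones at -0.28. These last 5 turned to 0.23, 0.16, 0.11, 0.32 and 0.03 with equal totals without the crystallins.

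The additive fit asked which genes differed with age in both genotypes, and again none passed an adjusted p of 0.05, with 1075 at an unadjusted p under 0.05. Crygf was nearest, lower at 4 months by -4.21 ± 0.25 (SE; adjusted p = 0.211), with Pgam2 (-2.37 ± 0.16; adjusted p = 0.211). Crygf passed without the genotype term (adjusted p = 0.0347) and with quantile normalization (adjusted p = 0.0183), and Col4a3 with the sum of all loci (adjusted p = 0.0492). With equal totals without the crystallins, again with an infinite prior df, 155 genes passed. Cryge (-3.29), Tnfaip6 (-2.42), Mpped2 (-1.89), Crygn (-1.61), the RNA 3' end processing gene Cpsf3 (-1.45) and Dip2a (-1.23) followed at an adjusted p of 0.391. Higher at 4 months, at the same adjusted p of 0.391, were Tinag (1.88), Psca (1.83), Lypd2 (1.81), Rpe65 (1.45), Lmo7 (1.22), Obfc2b (1.21), Gltscr2 (1.16) and the elongation factor gene Eef1d (1.12). Slurp1 (1.47 in WT and 2.02 in N101D) and Coro6 (1.27 and 1.58) were higher in both genotypes. Across genes the age differences of both genotypes had a Pearson correlation of 0.19 and a Spearman correlation of 0.23, with 26 genes at least 2-fold higher in both (3.96 for independent lists) and 29 lower in both (0.594).

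Camera with the preset correlation called 17 lists for age, none with an estimated correlation, where adjusted p was 0.747 for 16 of them and 0.876 for ribosomal proteins. Crystallins were lower by a median of -1.29 (preset adjusted p = 3.91e-15), and 8 of 16 passed when adjusted over the list alone against 0 over all genes. Lens capsule and matrix genes were lower by -0.58 (1.07e-06), with 9 of 16 adjusted over the list alone against 0 over all genes. Lower as well were sterol synthesis (-0.18, 4.62e-04), lens epithelium (-0.19, 0.00291), fiber membrane and cytoskeleton (-0.10, 0.00338), cell cycle (-0.27, 0.00348), blood (-1.35, 0.00470), cell adhesion (-0.14, 0.00498), denucleation (-0.11, 0.00830), oxidative phosphorylation (-0.02, 0.0382) and glycolysis (-0.17, 0.0452). Higher were retina neurons (0.43, 4.62e-04), pigmented tissue (1.37, 0.00121), immediate early genes (0.51, 0.00145), ribosomal proteins (0.35, 0.00348), cornea and conjunctiva (0.64, 0.00606) and the unfolded protein response (0.17, 0.0365). By fry the lowest adjusted p was 0.598. Among the lists called, the median, the mean and camera's direction again had the same sign. They differed for 9 lists not called: lens transcription factors, Na,K-ATPase, calcium handling, antioxidant response, fibrosis, FGF, BMP and Notch, autophagy, ubiquitin, and histones.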

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

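All tests in this part were chosen only after the results they bear on were seen. With 1 library per group, the differences between ages given here were not tested.

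A first set was noted because a genotype difference of 2-fold or more pointed in opposite directions at the ages of 2 and 4 months. The difference at 4 months minus that at 2 months was 4.11 for Col1a1, 3.65 for Sned1, 3.06 for Slc39a5, 2.92 for Hba-a1 and 2.88 for Hba-a2. It was -3.32 for Dock2, -2.83 for Dffb and -2.53 for Uox. Slc39a5 is listed at 0 in N101D at 2 months and in WT at 4 months. Dock2 has other loci that differ from the one used, and Uox shares its listed span with Dnase2b.

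Gene lists were noted where their medians lay outside the range of most random lists at both ages, on opposite sides. From 2 to 4 months the median genotype difference was 0.21 and then -0.35 for crystallins, -0.28 and 0.15 for FGF, BMP and Notch signalling, and 0.17 and -0.45 for ribosomal proteins. It was -1.41 and 0.18 for complement and antigen presentation, -1.22 and 1.26 for blood, and -2.61 and 0.14 for pigmented iris, ciliary body and RPE. Cornea and conjunctiva stood at -0.82 and 0.43, and vessels at -0.83 and 0.32. The opposite direction was lost for 4 of the 8 lists under an alternative that turned the value at 2 months, to -0.26 for crystallins and -0.29 for ribosomal proteins with equal totals without the crystallins, and to 0.80 for cornea and 0.33 for vessels with loci of status OK only. Among loci without a gene symbol, which no comparison used, the 24 shorter than 60 bases were higher in N101D at 2 months by a median of 1.92.

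The first pattern weighed is the 410 genes lower in N101D at 2 months. Lower depth of that library is argued against for 51 of them (12.4%). These reached 20 FPKM or more in the WT library, far above the level at which 24.6 M fragments would miss them. The median of all 410 genes was 4.53 FPKM in the WT library and 0.411 in the N101D library. Counting error of 1 kb of effective length at 1 FPKM spans 64.4% to 148% in the latter. Also, 410 genes were lower against 46 higher. These values argue against lower depth for the 410 genes as a set. For single genes under 20 FPKM the cutoff decides nothing. Less adjoining pigmented tissue in that library is a candidate explanation: all 14 measured markers were lower, with a median of -2.61, 0 of them stand on another list, and Dct, Gpnmb, Pmel, Tyrp1 (1.97 against 45.1 FPKM) and Trpm1 (5.31 against 41.8) were low together, but the abundant Ttr (16.3 against 37.3 FPKM; -1.15), Rpe65 (-0.62) and Oca2 (-0.29) differed far less, so the markers do not show a like loss of all pigmented tissue. A difference of genotype at 2 months only cannot be told apart from this, since each genotype had 1 library: that 399 of the genes (97.3%) lay within 2-fold at 4 months decides nothing, as 99.4% of all genes did. Sex is confounded with genotype at 2 months too, as Xist stood at 12.9 FPKM in N101D and 0.0744 in WT. Ddx3y, Eif2s3y, Kdm5d and Uty lay at 0.0367 to 0.303 FPKM in N101D and 1.94 to 11.6 in WT. How many of the 410 genes follow sex was not tested, and 13 of them lie on X or Y.

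The second pattern is the 10 genes of mean 50 FPKM or more that were at least 2-fold higher in N101D at 2 months, Dnahc7b, Jarid2, Kpna1, Filip1l, Zc3h7a, 2610528E23Rik, Mir715, Vwa3a, C230081A13Rik and Lars2, which shared 1 profile over the libraries: median 2.23 (SD 0.14) at 2 months, 1.14 (SD 0.20) at 4 months and -1.11 with age in WT. Inflated values of short loci stay undecided. Unnamed loci under 60 bases had a median of -0.34 (standard error 0.32) at 4 months, where the 10 genes were higher. In the other comparisons these loci moved in the direction of the genes, by 1.92 at 2 months, -0.73 with age in WT and -3.35 with age in N101D. Unnamed loci of 80 to 100 bases stood at 0.53 at 4 months. A difference in the genes' own transcripts stays open: among 8 second loci of 5 of the genes on either strand the ratio of N101D to WT at 2 months reached from 0.749 to 5.15 (a locus of Zc3h7a), while the 4 on the same strand lay between 1.10 and 1.24, and the other 5 genes have none at 1 FPKM or more. Ribosomal RNA reads as a common source may account for them and stay undecided, as Mir715 lies between Esp23 and Pgk2 and so does a ribosomal RNA gene in the RefSeq annotation of GRCm38, but 0 of the other 9 genes had an annotated exon with an 18-base stretch of the transcripts at that locus, and introns and other parts of the ribosomal RNA were not searched.

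The third pattern is that immediate early genes were higher and ribosomal protein genes lower in N101D at 4 months. A trend with transcript length is argued against for the immediate early genes: with the median of 20 length bins taken off, their median was 0.58 (from 0.59). The ribosomal median was -0.40 (from -0.45), but no bound was set for that list. Lengths were those of the longest annotated transcript, which need not be the one expressed, with list medians of 2553 and 1120 bases. They were known for 87.7% of genes and for all 15 and 27 members. The time between death and lysis of the tissue could differ between preparations, and the same list differed by 0.29 between the WT libraries of 4 and 2 months. A difference of genotype, for which the list's median at 2 months was 0.0433, cannot be told apart from it, since each library is 1 preparation.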

How the results depend on the processing

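All alternatives were planned except 2 chosen after seeing the data, symbols on 1 stranded locus only and, for limma, equal totals without crystallins. Of 183 counts and correlations under an alternative, 115 stayed within 1.5 times and 68 moved further. Of 1440 list medians 1088 kept their place, 330 moved and 22 were counted as changing sign. Of 2872 values of named genes 2699 kept their side of 2-fold, 172 crossed it and 1 was counted as changing sign. A change of sign was counted only for list medians outside the range of most random lists before the alternative was applied. For named genes it was counted only from differences of 2-fold or more. Other values may have changed sign without being counted or listed here. Median centring and symbols on 1 stranded locus moved none of the counts by over 1.5 times. Unless said otherwise, the cause was not tested. Counts are given as higher and lower.

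By construction, a 1.5-fold threshold counted more genes: 174 and 937 for genotype at 2 months, 227 and 173 at 4 months, 471 and 309 for age in WT, 1761 and 526 for age in N101D. A 3-fold threshold counted 17 and 177, 7 and 5, 12 and 15, and 202 and 39, in the same order. A pseudocount of 0.1 gave 103 and 781, 109 and 81, 201 and 145, and 1203 and 242, with the genotype difference larger by 1 or more at 4 months for 1193 genes, smaller for 259 and opposite for 44. A pseudocount of 5 gave 12 and 112, 15 and 2, 23 and 27, and 129 and 51, with 161, 44 and 2.

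With fewer genes, a filter at 5 FPKM left 26 and 208 for genotype at 2 months, 14 lower at 4 months and 313 higher with age in N101D, with 318, 88 and 5 for the difference between ages. List medians counted as changing sign were, at 2 months, cell cycle (-0.16), immediate early genes (-0.0228) and vessels (0.18), and histones with age in N101D (0.38). Loci of status OK only left 29 and 189 at 2 months, 25 and 21 at 4 months, 40 higher with age in WT and 261 in N101D, with 316 and 94 for the difference between ages. Medians counted as changing sign were cell cycle (-0.16), cornea (0.80) and vessels (0.33) at 2 months, and histones (0.48), complement (-0.32) and vessels (-0.0204) with age in N101D. The muscle list had no gene left under either, nor the macrophage list at 5 FPKM, so neither has a median there. Without a filter histones turned to 0.0230 at 4 months and to 0.0209 with age in N101D.

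Equal totals without crystallins gave 24 and 747 at 2 months and 1427 and 51 with age in N101D, with 1279, 53 and 16 for the difference between ages. Here 10 genes of high FPKM held 37.3% of the remaining total in N101D at 2 months against 11.3%, 11.7% and 5.17% in WT at 2 months, N101D at 4 months and WT at 4 months, so that library was scaled by 0.775 and the others by 1.08, 1.08 and 1.10. Medians counted as changing sign at 2 months were crystallins (-0.26), cell cycle (-0.22), immediate early genes (-0.29) and ribosomal proteins (-0.29). With age in N101D they were lens epithelium (0.23), denucleation (0.16), cell cycle (0.11), sterol synthesis (0.32) and histones (0.0276). limma then called 61 genes for genotype and 155 for age with an infinite prior df, against 0 and 0 with the values as deposited. Upper quartile scaling gave 202 genes lower with age in N101D. Quantile normalization turned crystallins at 2 months to -0.16 and Cryba4 with age in N101D to 0.44. The sum of all loci gave 71 higher at 4 months and 14 opposite genes. For age limma called 1 gene without the genotype term and 1 with quantile normalization, Crygf both times (-4.21 and -3.65), and 1 with the sum of all loci, Col4a3 (5.38), named after its value was seen. For genotype every other limma alternative called 0.

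Depth limits what 24.6 M fragments can show in N101D at 2 months, where 1 kb of effective length at 1 FPKM rests on 15.8 to 36.4 reads. No count at 2 months or for age in N101D can be made without that library, and leaving out any library leaves limma 0 residual df. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers that would pair animals, and the additive limma fit instead sets the genotypes side by side within each age. Confidence bounds and DESeq2 were not run, since the tables as used hold neither bounds nor counts. Groups are too small for other splits of the samples.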

Other observations

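No test in this part was planned, and the values are given without explanation. Photoreceptor genes were lower in N101D than in WT at 4 months. The rod genes Gnat1, Pde6a, Pde6b, Pde6g and Prph2 differed by -0.63, -0.67, -0.70, -0.73 and -0.64, and the rod genes Sag and Nrl by -0.95 and -0.92. The cone genes Opn1sw, Opn1mw, Arr3 and Gnat2, all below 10 FPKM, differed by -0.61, -0.58, -0.64 and -0.45. At 2 months the same genes had no common direction: Sag stood at 61.3 against 59.4 FPKM, while Opn1sw differed by -0.67 and Opn1mw by 0.77. Rlbp1, a gene of Müller glia and pigment epithelium on the same list, differed by -0.89 at 2 months and -0.25 at 4 months.

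Among the 12 immediate early genes below 2-fold at 4 months, Dusp1 (12.3 against 5.71 FPKM), Nr4a1 (2.94 against 1.10), Btg2 (14.1 against 7.96), Ier2 and Zfp36 were higher in N101D by 0.99, 0.91, 0.75, 0.73 and 0.59. Klf4 (0.34), Fosl2 (0.28), Jun (0.27), Jund (0.07), Ier3 (0.03), Fosl1 (0.02) and Klf6 (-0.06) lay closer to 0.

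Jarid2 has a locus on the opposite strand that stood at 3188 FPKM in N101D and 715 in WT at 2 months, and at 702 and 408 at 4 months. Among loci without a gene symbol, the median difference at 2 months was 0.93 for the 64 loci of 60 to 80 bases, 0.69 for the 42 of 80 to 100 bases and 0.08 for the 1160 in the longest class. At 4 months these medians were 0.15, 0.53 and 0.07.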
